A study of Mus musculus with 2 samples.

How the data were processed

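The sources used here describe 2 libraries of dissociated MC38 tumours, 1 per group, made with a 10x 3' kit with about 6000 cells loaded and 3000 targeted, per the labels' protocols. The authors deposited unfiltered UMI count matrices of 32285 features, which Cell Ranger made, per the file headers and the submitters' processing notes. The genome build and annotation are not given in the sources used here, and how reads shared between similar genes were assigned is not either. Gene positions and types came from GENCODE vM21 on GRCm38, in which 99.6% of the feature identifiers were found. The group labels read Mbtps1 WT and Mbtps1 KD, and the series text says knockout. The groups are called control and knockdown here, after the labels.

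The matrices listed 1688458 barcodes for control and 1769772 for knockdown. A barcode was kept with at least 500 UMIs, at least 250 genes, at most 20% mitochondrial UMIs and a profile unlike that of empty droplets. That profile came from barcodes of at most 100 UMIs, and each barcode was tested with 1000 draws of a Dirichlet-multinomial at a false discovery rate of 0.01, while barcodes of at least 3000 UMIs were taken as cells. Of 16874 control and 26702 knockdown barcodes with at least 500 UMIs, 5115 and 9701 were like empty droplets. Scrublet then removed 461 and 801 doublets, which left 11112 and 16005 cells. Barcodes of 101 to 400 UMIs held 7.88% of control and 10.3% of knockdown UMIs. In both libraries the cell numbers exceed the 3000 cells targeted and also the about 6000 loaded, and the sources used here do not say why.

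Counts were scaled to 10000 UMIs per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 27 clusters, without integration of the libraries. T/NK and myeloid cells were clustered again into 13 and 18 subclusters. A cluster with Xist below 20 CPM could only be tumour or unnamed, and any other took the host class for which it counted the most fixed markers, at least 3, each at 20 CPM or more and at least 25% of the highest cluster's CPM. The 7 tumour clusters had Xist below 20 CPM and markers of at least 10 CPM and 3 times the host median. These thresholds were set after the data were seen and after earlier versions with a share of 15% or other limits for tumour markers, with the counts per library in view, and they left 0.234% of control and 0.387% of knockdown cells unnamed. Myeloid subclusters 1, 2, 8 and 12 had a dendritic but no macrophage marker among their 10 leading genes within the myeloid cells. Each still counted 10 of the fixed macrophage markers. They kept the macrophage name because each had at least 1 macrophage and 0 markers of another class among its 10 leading genes against cells outside the myeloid group, and an added alternative leaves them out. Tumour cluster 10 counted 4 fibroblast and 3 tumour markers and was named by its low Xist, with 0 tumour markers among its 10 leading genes, and another added alternative leaves it out. The clusters moved slightly with the numerical settings of the computer, which were then fixed, and another seed was added as an alternative.

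UMIs were summed per class and library and given as CPM of the class sum. Ratios carry 95% exact Poisson intervals and shares 95% Clopper-Pearson intervals, for counting error only. No test across genes was made, because each group holds 1 library and cells of 1 tumour sample are not replicates. For each of 24 gene lists, fixed before the data were seen, the median log2 ratio of members with at least 20 UMIs was set against 10000 random lists matched for expression, with 50 genes on each side to draw from. The lists are site-1 protease pathway, cholesterol synthesis, fatty acid synthesis, ER chaperones, integrated stress response, lysosome, interferon, MHC class I, MHC class II, chemokines, checkpoint ligands, cytotoxic, exhaustion, naive and memory T cells, inflammatory and alternative macrophages, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, matrix, dissociation, heat shock, nuclear RNA and p53 targets. The authors' CPM or ratios were not among the deposited files used here, so all CPM and ratios were computed from counts.

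Genes were named by a rule fixed before the data were seen. It took Mbtps1 and its pathway list in tumour-like cells. In each class of at least 200 cells in both libraries it also took the 10 genes with the highest and the 10 with the lowest ratio, ranked by the interval end nearest 1, among genes with a CPM of at least 50 in 1 library and at least 50 UMIs over both. A gene was left out if its higher CPM was not above that of the library's empty droplets, or if it was mitochondrial, ribosomal, a haemoglobin, unnamed or a receptor segment. For each list it took the 2 members with the highest mean CPM and the members with the highest and lowest ratio. The members printed are a selection made after the values were seen, and some genes that the rule takes are not reported here. Fn1, Sparc and Col1a1 in tumour-like cells lie outside the rule and were chosen after their values were seen. The CPM of Cd274 and Mki67 in tumour-like cells, Mki67 in macrophages, Gzmb and Ifng in T-like cells and Prf1 in NK-like cells were added after the values were seen, from genes fixed for the shares of cells. Shares of cells with a UMI used cells thinned to 500 UMIs for 8 genes fixed in advance. Free RNA was estimated per class from genes of cells of another kind against the empty droplets.

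The steps were tested on simulated data, with class sums drawn as Poisson counts, which lack the clumping of UMIs in single cells. Coverage near 95% follows from such draws, so it checks the code and not the intervals of clumped genes. Of lists of unaltered genes, 5.5% fell outside the 2.5th to 97.5th percentile in tumour-like cells. In T-like and CD8 T-like cells 8.5% did. For the comparison of tumour-like cells, with 200 genes altered, the interval held the true ratio of 96.9% of altered genes at a fold of 1.25 (17126 genes), 95.5% at 1.5 (17127 genes), 93.4% at 2 (17124 genes) and 97.4% at 4 (17148 genes). The median log2 ratios of the raised genes were 0.32, 0.57, 1.00 and 1.99 for these folds. A mix of clusters taken alone gave −0.10 for the cholesterol list, −0.04 for the ER chaperones, −0.13 for MHC class I, −0.26 for the matrix and 0.26 for the cell cycle. Of 4000 simulated empty barcodes per library, 0 were called cells. That says little, because the correction for many tests can hardly call any barcode in a set that is all empty. Before it, 1.05% of control and 1.2% of knockdown ones had a p of at most 0.01 in the Dirichlet-multinomial test. For the explanations weighed in the closing section, a stricter rule taken up after the first results were seen was dropped again for the rules as first written, which moved 1 verdict, that on depth for the cholesterol list. Alternatives to each choice were tried, of which 15 settings were planned before the data were seen and 9 were added after. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, numba 0.67.0, statsmodels 0.14.6, igraph 0.11.9 and matplotlib 3.10.9.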

Results

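Single-cell RNA sequencing was done on tumours of MC38, a mouse colon adenocarcinoma cell line. The series holds 2 droplet libraries, 1 from a control tumour sample and 1 from a sample labelled Mbtps1 knockdown, which the series text calls a knockout. The control library held 177399315 UMIs (unique molecular identifiers, 1 per captured RNA molecule), of which 81.5% lay in 11112 kept cells with a median of 8158.5 UMIs. The knockdown library held 174190399 UMIs, of which 75.8% lay in 16005 kept cells with a median of 4867 UMIs. The comparison of the 2 libraries asks how loss of MBTPS1 in the tumour relates to the tumour cells and to the immune cells around them. With 1 library per group, no difference reported here has a replicate check, and the 95% intervals cover counting error only.

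Mbtps1 RNA was lower in the tumour-like cells of the knockdown library and near equal in the macrophages and T cells of the 2 tumours. The gene encodes site-1 protease, which cuts the membrane-bound SREBP and ATF6 transcription factors and the GNPTAB precursor in the Golgi. What was altered in the gene is not given in the sources used here, so 3' tags can check the amount of RNA but not whether the protein is intact.

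The gene (ENSMUSG00000031835, chromosome 8, 119508156 to 119558735 on the minus strand of GRCm38) had 2995 UMIs in control tumour-like cells and 1252 in knockdown ones. These counts were 28.9 CPM (UMIs of the gene scaled to 1e6 UMIs of the class, interval 27.8 to 29.9) and 12.3 CPM (11.6 to 12.99), a ratio of knockdown over control of 0.425 (0.398 to 0.454). Mbtps1 was 2.35-fold lower, and its ratio was below 1 in all 7 tumour clusters, from 0.273 to 0.532. Macrophage/monocyte-like cells had 19.5 and 19.4 CPM, a ratio of 0.994 (0.873 to 1.13), and T-like cells had a ratio of 0.955 (0.702 to 1.31). The interval of the ratio also held 1 in NK-like cells (0.860, 0.520 to 1.41), fibroblast-like cells (0.948, 0.661 to 1.35) and endothelial-like cells (0.680, 0.366 to 1.22).

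**Figure D1:**
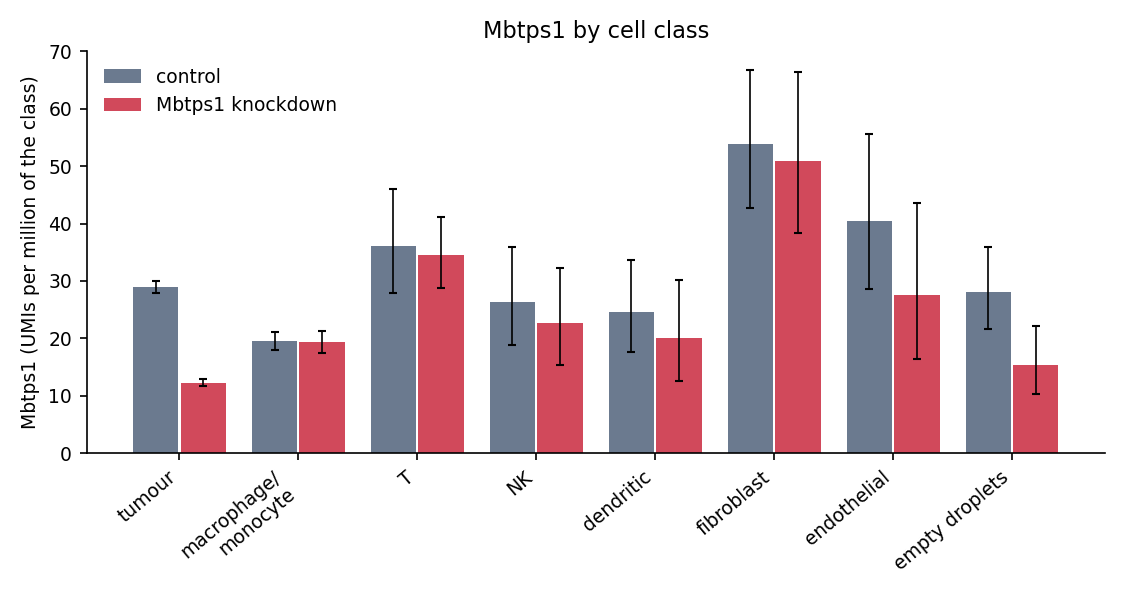
Mbtps1 in CPM by cell class in the control and the knockdown library, with 95% Poisson intervals as bars. Tumour-like cells had 28.9 CPM in control and 12.3 in knockdown, while macrophage/monocyte-like cells had 19.5 and 19.4.

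The knockdown tumour held a larger share of T cells, and most of that surplus was CD8 T cells, the cells that kill tumour cells. Its regulatory T cells, which restrain that killing, made up the same share of cells as in the control. Gamma-delta T cells and neutrophils also had larger shares of the kept cells in the knockdown tumour. Among deeper cells no direction could be read for neutrophils, and the gamma-delta share was not recomputed. Macrophages and monocytes, the most numerous immune cells of both tumours, had a smaller share, as did dendritic cells.

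CD8 T-like cells were 3.09% of kept cells in control (343 cells, exact Clopper-Pearson interval 2.77 to 3.43) and 8.13% in knockdown (1301 cells, 7.71 to 8.56), a ratio of 2.63. Among immune-like cells their share was 5.72% (5.15 to 6.34) and 16.9% (16.1 to 17.8), a ratio of 2.96. All T-like cells were 4.82% (4.43 to 5.24) of kept cells in control and 10.5% (10.0 to 10.97) in knockdown. Regulatory T-like cells were 1.37% in both libraries, so that they made up 28.4% (24.6 to 32.4) of control T-like cells and 13.1% (11.5 to 14.8) of knockdown ones. Gamma-delta T-like cells were 0.189% (0.117 to 0.289) and 0.675% (0.554 to 0.814) of kept cells. They numbered 21 and 108, with a median of 1485 UMIs, and their share was not recomputed among deeper cells. NK-like cells differed little, with 2.46% (2.18 to 2.76) and 2.92% (2.66 to 3.19). Macrophage/monocyte-like cells were 43.1% (42.2 to 44.0) in control and 31.4% (30.7 to 32.2) in knockdown, a ratio of 0.730. Within that class, monocyte-like cells were 5.74% (5.10 to 6.44) and 8.94% (8.17 to 9.76). Dendritic-like cells were 2.38% (2.10 to 2.68) and 1.58% (1.39 to 1.79). Tumour-like cells were 40.4% (39.5 to 41.3) and 48.6% (47.8 to 49.3). Epidermis-like cells, which lie outside the tumour proper, were 2.02% and 0.712%, so the 2 samples may also have differed in how much skin they held. Fibroblast-like cells were 1.66% and 1.17%, and endothelial-like cells 1.06% and 0.775%.

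The knockdown cells were shallower (T-like median 1859 UMIs against 2691 in control), and the 500-UMI minimum and free RNA act on these shares. Among cells of at least 2000 UMIs the T-like ratio was 1.63 in place of 2.17, and the neutrophil-like share, 0.549% (0.420 to 0.705) and 1.19% (1.03 to 1.37) of all kept cells, had a ratio of 0.632 (0.118 to 3.18), from which no direction can be read.

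**Figure D2:**
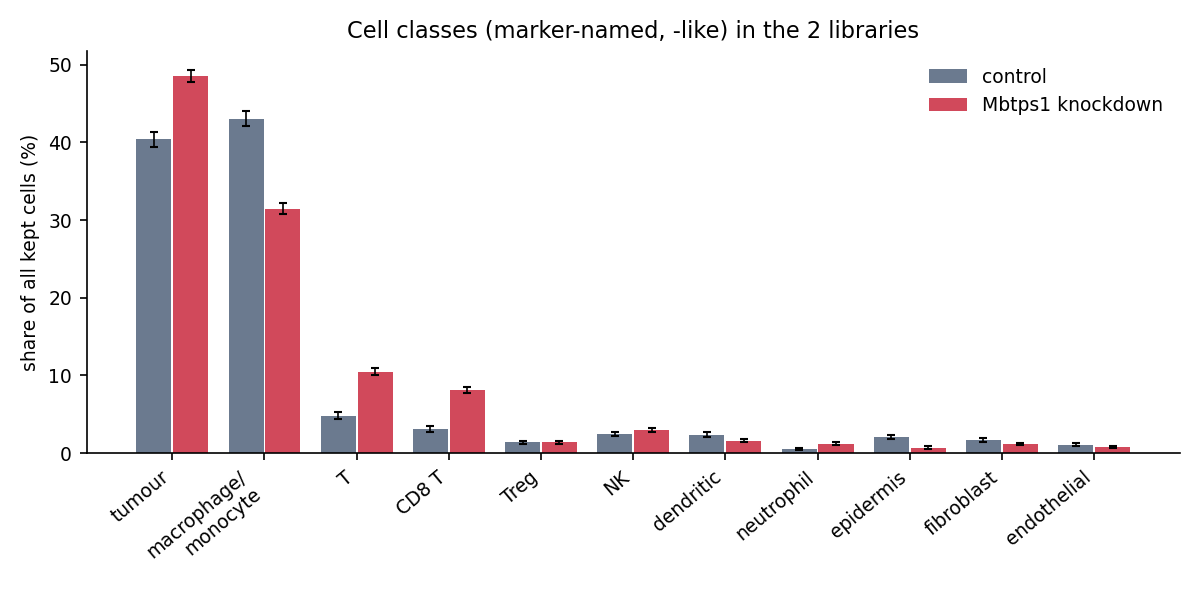
Shares of kept cells in percent by cell class in the 2 libraries, with 95% Clopper-Pearson intervals as bars. CD8 T-like cells were 3.09% in control and 8.13% in knockdown, and macrophage/monocyte-like cells 43.1% and 31.4%.

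In tumour-like cells, some gene lists downstream of site-1 protease substrates were slightly lower in the knockdown and others were not. Cholesterol synthesis genes are targets of SREBP2, and chaperones of the endoplasmic reticulum are targets of ATF6, and both lists had lower medians, while fatty acid synthesis genes, targets of SREBP1, did not. Lysosomal enzymes, which GNPTAB tags for transport to the lysosome, were lower as well, but this list turned when the tumour clusters had equal weight. Among the substrates themselves Creb3 RNA was lower and the scarce Creb3l1 RNA higher.

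Clusters 4 and 10 held more of the control tumour-like cells and clusters 0, 1, 3 and 11 more of the knockdown ones, so each tumour median mixes levels within clusters with the mix of clusters. The cholesterol synthesis list had a median log2 ratio of −0.18 (−0.22 to −0.14), which placed it at percentile 0.01 of 10000 random lists matched for expression. With the clusters at the same weight its median was −0.07, and its interval lay below 0 in 3 of 7 clusters, with medians of 0.05 and 0.02 in clusters 4 and 10. Fdps had 292 CPM in control and 209 in knockdown, a ratio of 0.715 (0.703 to 0.728), and Mvk a ratio of 0.669. The fatty acid synthesis list, driven by SREBP1, had a median of 0.08 (0.04 to 0.10) at percentile 78.0. The ER chaperone list had a median of −0.22 (−0.23 to −0.18) at percentile 0.02, with a median below 0 in 7 of 7 tumour clusters and −0.14 at the same weight. Sdf2l1 had 25.5 and 17.4 CPM, a ratio of 0.684 (0.643 to 0.726), whereas the abundant chaperones Hsp90b1 and Calr had ratios of 0.997 and 0.914, and Canx was higher at 1.18. The lysosome list had a median of −0.15 (−0.18 to −0.10) at percentile 0.04, of 0.04 at the same weight and of −0.46 among cells of 10000 to 20000 UMIs. Its members Cd63 and Neu1 had ratios of 0.741 and 0.672, and Ctsl 1.05. The list of the site-1 protease pathway itself had a median of 0.05 (0.01 to 0.11) at percentile 37.1. Within it Srebf2 was higher at 1.15 (1.12 to 1.18), as were Gnptab at 1.17 (1.12 to 1.23) and Mbtps2 at 1.14 (1.08 to 1.22). Srebf1, Insig1 and Atf6 had ratios of 1.02, 0.952 and 0.963, and Creb3 had 40.6 and 26.2 CPM, a ratio of 0.646 (0.615 to 0.678), while Creb3l1 had 34 and 66 UMIs, a ratio of 1.98 (1.29 to 3.08). The integrated stress response list had a median of −0.06 (−0.08 to −0.03) at percentile 6.87, with Nupr1 at 0.570, although Psat1 and Phgdh, which make serine, were higher at 1.33 and 1.14.

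**Figure D3:**
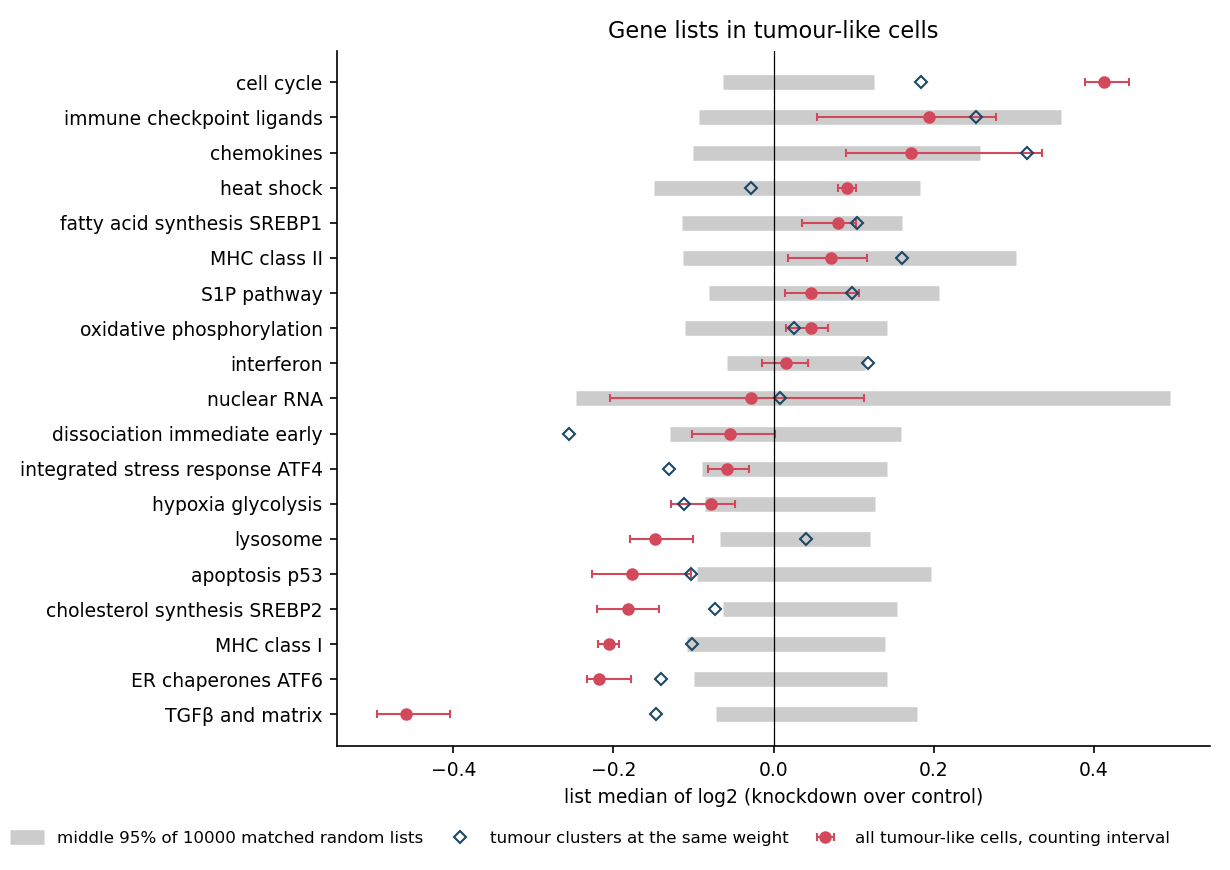
Median log2 ratio of knockdown over control of the gene lists apart from those of other cell types in tumour-like cells, with 95% counting intervals as thin bars, grey bars for the middle 95% of 10000 matched random lists and open diamonds for tumour clusters at the same weight. Matrix, ER chaperone, MHC class I, cholesterol, p53 target and lysosome lists lay below that range, and the cell cycle list above it.

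Genes by which tumour cells show themselves to T cells differed in both directions in the knockdown. Antigen presentation genes of MHC class I were lower as a list, while Nlrc5, the activator of that class, was higher. The interferon list was near equal in the class as a whole and higher within most tumour clusters, with guanylate-binding proteins higher and Irf7 and Bst2 lower. Cxcl9, a chemokine that draws T cells, was lower in the knockdown tumour cells, and Cd274, which encodes PD-L1, was higher.

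The MHC class I list had a median of −0.21 (−0.22 to −0.19) at percentile 0.03, and −0.10 with the tumour clusters at the same weight. Its interval lay below 0 in 6 of 7 clusters and above 0 in cluster 3. H2-D1 had 1936 and 1258 CPM, a ratio of 0.650 (0.645 to 0.655), and H2-T23 a ratio of 0.583, while Nlrc5 had 51.3 and 71.6 CPM, a ratio of 1.40. B2m had a ratio of 0.979 and a log2 ratio of 0.13 at the same weight, so its direction turned. The interferon list had a median of 0.02 (−0.01 to 0.04) at percentile 41.8, of 0.12 (0.09 to 0.15) at the same weight, with an interval above 0 in 5 of 7 clusters, and of −0.29 (−0.31 to −0.24) among cells of 10000 to 20000 UMIs. Irf7 had 34.6 and 17.5 CPM, a ratio of 0.506 (0.478 to 0.536), and Bst2 a ratio of 0.797, but Gbp2 and Gbp4 had ratios of 1.19 and 1.38. Cxcl9 had 208 CPM in control and 102 in knockdown tumour-like cells, a ratio of 0.491 (0.480 to 0.503). Cxcl10, at 765 and 796 CPM, turned direction with cells at equal weight, and Cxcl1, which attracts neutrophils, had 40.4 and 107 CPM. Cd274 had 51.1 and 74.1 CPM, a ratio of 1.45 (1.40 to 1.502). The chemokine list had a median of 0.17 (0.09 to 0.34) at percentile 84.2, the checkpoint ligand list 0.19 (0.05 to 0.28) at percentile 75.0 and the MHC class II list 0.07 (0.02 to 0.12) at percentile 45.0.

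Proliferation genes were higher and matrix genes lower in the knockdown tumour cells. Top2a, Cdc6 and Mki67 serve DNA replication and division. Collagen, fibronectin and tenascin genes build the matrix around cells and are targets of TGF-beta. Its ligand gene Tgfb3 was lower too, but less so within each tumour cluster than in the class as a whole. The proliferation and matrix contrasts were both weaker when the tumour clusters had the same weight.

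The cell cycle list had a median of 0.41 (0.39 to 0.44), above all 10000 random lists, of 0.18 with the tumour clusters at the same weight and of 1.44 (1.39 to 1.501) among cells of 10000 to 20000 UMIs. Top2a had 213 and 333 CPM, a ratio of 1.57, Cdc6 a ratio of 1.75, Hmgb2 a ratio of 1.53, and Mki67 59.6 and 83.0 CPM, a ratio of 1.39 (1.35 to 1.44). Cdc20 had a ratio of 1.01. The matrix list had a median of −0.46 (−0.50 to −0.40), below all 10000 random lists, with 11 of 26 members at least 1.5 times lower. Its median was −0.15 at the same weight and −0.19 with 10% free RNA subtracted. The interval lay below 0 in 4 of 7 clusters, while cluster 0 had a median of 0.17 (0.0028 to 0.24). Col3a1 had 1809 and 1043 CPM, a ratio of 0.576, Tnc 19.8 and 0.872 CPM, a ratio of 0.0440 (0.0352 to 0.0544), while Vim had a ratio of 0.932 and Loxl2 was higher at 2.60. Fn1, Sparc and Col1a1, chosen after their values were seen, had ratios of 0.478, 0.587 and 0.190. The p53 target list had a median of −0.18 (−0.23 to −0.10) at percentile 0.27. The hypoxia and glycolysis list had −0.08 (−0.13 to −0.05) at percentile 3.25, and the oxidative phosphorylation list 0.05 (0.02 to 0.07) at percentile 66.8. Lists that record handling of the tissue were close to 0, with −0.05 (−0.10 to 0.00) at percentile 13.02 for dissociation, 0.09 (0.08 to 0.10) at percentile 83.4 for heat shock and −0.03 (−0.20 to 0.11) at percentile 26.9 for nuclear RNA. Lists of genes of other cell types can carry free RNA, which was an estimated 2.499% of control and 4.00% of knockdown tumour-like UMIs. Their tumour medians were 0.67 (0.43 to 0.76) at percentile 99.9 for cytotoxic genes and 0.62 (0.44 to 0.75) at percentile 99.8 for exhaustion. The naive and memory T cell list had 0.45 (0.02 to 0.66) at percentile 97.8. It turned to −0.51 with thinned cells and to −0.61 with the estimated free RNA subtracted. The medians were 0.13 (−0.04 to 0.30) at percentile 59.8 for inflammatory and 0.06 (−0.06 to 0.19) at percentile 35.9 for alternative macrophages.

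The genes with the largest tumour differences on the high side included the chemokine Cxcl1, the guidance receptor Nrp2 and the neurturin receptor Gfra2. Those on the low side included the imprinted RNA H19, the elastic-fibre gene Mfap4 and the ligand gene Tgfb3. Most of these genes lay on the same side of 1 in every tumour cluster. H19, Robo2, Mfap4, Pld5, Rgs20, Itgbl1, Cxcl1, Nupr1, Psat1 and Phgdh also lead tumour clusters, so their totals carry the mix of clusters.

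The 2282 genes that passed the CPM and UMI minimums were ranked by the interval end nearest 1. The highest were Gfra2 with 16.6 and 51.4 CPM (ratio 3.095, 2.93 to 3.27), Nrp2 with 40.1 and 111 CPM (2.76, 2.67 to 2.87), Cxcl1 (2.66, 2.56 to 2.76) and Nav2 (2.59). Dennd5b, Itgbl1, Fam20b, Pld5, Junos and Rgs20 followed with ratios of 2.26, 2.24, 2.18, 2.18, 2.15 and 2.14. Junos is read from the strand opposite Jun, and whether the counting kept the strands apart is not given in the sources used here. The lowest was Mfap4 with 80.2 and 5.71 CPM, a ratio of 0.0713 (0.0654 to 0.0775). H19 had 896 and 269 CPM (0.300, 0.296 to 0.304), and Tgfb3 94.998 and 29.3 CPM (0.309, 0.296 to 0.322). Rgcc, Aspn, Ier5l, Robo2, Dpt, Lrrc17 and Ebf1 had ratios of 0.340, 0.347, 0.348, 0.351, 0.382, 0.382 and 0.408. Aspn, Dpt and Lrrc17 carry the mix of clusters as well. Their cluster ratios reached 1.07, 1.02 and 1.02, with an interval below 1 in 4, 4 and 5 of 7 clusters. The total ratios of Tgfb3, Nav2, Dennd5b and Fam20b also carry it, as they lie outside the range over the clusters. Those ranges were 0.370 to 0.808, 1.30 to 2.41, 1.19 to 2.10 and 1.32 to 2.17. Ebf1 had cluster ratios of 0.390 to 0.752, with its total near the low end. Of these 20 genes, Gfra2, Nrp2, Dennd5b, Itgbl1, Fam20b, Pld5, Rgs20, Junos, H19, Tgfb3, Rgcc, Ier5l and Ebf1 had an interval on the same side of 1 in 7 of 7 tumour clusters.

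**Figure D4:**
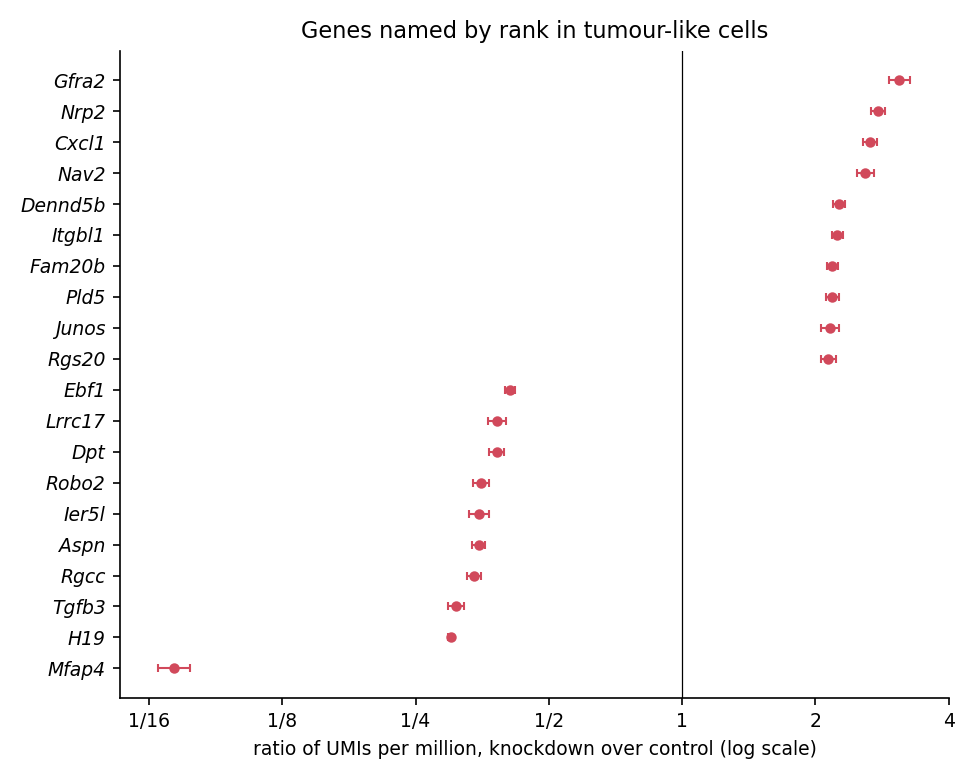
Ratio of knockdown over control, on a log axis, of the 20 named tumour genes with 95% counting intervals as bars. Gfra2 was highest at 3.095 and Mfap4 lowest at 0.0713.

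Macrophages and monocytes of the knockdown tumour had higher RNA of inflammatory genes. Cxcl9, the chemokine through which macrophages recruit T cells, was higher there, although it was lower in the tumour cells. Saa3, Cxcl2 and Clec4e, genes of acute inflammation, were among the highest, and Ccl8 was higher as well. Of the dissociation list, Egr1 was higher and Btg2 lower. Genes of the alternative macrophage list went both ways, with Arg1 and Trem2 lower and Chil3 and Retnla higher. The interferon list as a whole was near equal, and Ifit2 and Ifit3 were lower.

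The inflammatory list had a median of 0.41 (0.30 to 0.44), above all 10000 random lists. Cxcl9 had 1448 CPM in control and 2454 in knockdown, a ratio of 1.69 (1.67 to 1.72), and Cxcl10 a ratio of 1.15 (1.12 to 1.17). With every cell thinned to 500 UMIs and 0 cells left out, 29.6% (28.3 to 30.9) of control and 42.0% (40.7 to 43.4) of knockdown macrophage/monocyte-like cells held a Cxcl9 UMI. The median depths were 6037 and 3694 UMIs, the unthinned shares 59.2% and 66.9%, and thinned T-like cells, which should lack the gene, held it in 3.36% and 6.08%. Saa3 had 29.8 and 80.7 CPM (2.71, 2.49 to 2.94), with 414 of its 919 control UMIs in 1 cell and a log2 ratio of 2.19 without the top cell of each library. Chil3 had 48.5 and 112 CPM (2.31, 2.17 to 2.47), Cxcl2 432 and 769 CPM (1.78) and Ccl8 1058 and 1745 CPM (1.65). Egr1, Tnfaip2, Clec4e and Kdm6b had ratios of 2.15, 1.90, 1.59 and 1.58. Retnla was also among the highest, but 993 of its 2962 knockdown UMIs lay in 1 cell. Btg2, Ifit3, Tmem37, Hdac9 and Bag3 were the lowest with ratios of 0.581, 0.614, 0.628, 0.630 and 0.665, followed by Zdhhc14, Ifit2, Cxcl14 and Rgs10 with 0.698, 0.700, 0.702 and 0.705. Trem2 had 594 and 439 CPM (0.739, 0.721 to 0.758) and Arg1 1163 and 903 CPM (0.776, 0.763 to 0.790). Cxcl9, Ccl8, Saa3, Arg1, Trem2, Chil3, Retnla, Ifit2, Ifit3, Hdac9 and Zdhhc14 also lead macrophage or monocyte clusters or subclusters. The interferon list had a median of −0.03 (−0.05 to 0.04) at percentile 11.2, with Gbp2 at 1.38 and Bst2 at 0.827. The MHC class II list had −0.08 (−0.10 to −0.06) at percentile 14.1, and H2-Ab1, at 0.960, turned direction without the subclusters led by a dendritic marker. Mki67 and Spp1, the latter at 1.08, turned direction with thinned cells. The cell cycle list had a median of 0.27 (0.19 to 0.29), above all 10000 random lists, and free RNA was an estimated 5.30% of control and 9.28% of knockdown UMIs in this class.

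T cells of the knockdown tumour were more numerous, while their cytotoxic list was near equal to that of the control. Ccl5, a chemokine of effector CD8 T cells, was higher, and granzyme genes were lower. Genes of activated regulatory and helper T cells, such as Tnfrsf4, Izumo1r and Ctla4, were lower, and regulatory cells were a smaller part of the class. Within CD8 T cells, Pdcd1 and Entpd1 were higher and Tnfrsf9 lower, all genes of the exhaustion list. The naive and memory list had a lower median there, though its members Ly6c2 and Bach2 were not lower. NK cells also had lower granzyme and perforin RNA.

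The cytotoxic list had a median of 0.01 (−0.13 to 0.08) at percentile 60.0 in T-like cells and of −0.05 (−0.22 to −0.01) at percentile 20.1 in CD8 T-like cells. The T-like median was 0.18 among cells of at least 2000 UMIs and 0.14 with the estimated free RNA subtracted. In T-like cells Gzmb had 1484 and 878 CPM (0.591, 0.562 to 0.623), and Gzmc, Gzme and Gzmf had ratios of 0.207, 0.342 and 0.369. The last 3 belong to a family of similar genes whose reads could be shared, so their separate values are uncertain. With cells thinned to 500 UMIs and 0 cells left out, 29.9% (26.0 to 33.9) of control and 21.5% (19.5 to 23.5) of knockdown T-like cells held a Gzmb UMI. The median depths were 2691 and 1859 UMIs, the unthinned shares 50.9% and 44.2%, and thinned macrophage/monocyte-like cells held it in 0.272% and 0.139%. Regulatory T-like cells had the most Gzmb, with 2810.5 and 1788 CPM (0.636), so their smaller part of the class adds to the T-like difference. In CD8 T-like cells Gzmb had a ratio of 0.720 (0.675 to 0.769), but the shares of cells with a UMI overlapped, at 21.3% (17.1 to 26.0) and 19.3% (17.2 to 21.5), with unthinned shares of 43.1% and 43.7% at median depths of 3142 and 2018 UMIs. Ccl5 had 1774 and 3952 CPM (2.23, 2.14 to 2.32) in T-like cells and a ratio of 2.07 (1.99 to 2.15) in CD8 T-like cells. CD8 subcluster 1, which Ccl5 leads, held 33 of 343 control and 385 of 1301 knockdown CD8 T-like cells, so Ccl5 carries the mix of subclusters. Tnfrsf4 had 492 and 213 CPM (0.434), Ifi27l2a 2191 and 1045 CPM (0.477), Izumo1r a ratio of 0.430 and Ctla4 0.674. Tnfrsf4, Izumo1r and Ctla4 lead a regulatory T cluster, so they follow its part of the class. Cd163l1 and Trdc, with ratios of 4.19 and 2.31, mark gamma-delta T cells and follow the share of those cells. Ifng had a ratio of 0.865 (0.7995 to 0.935) in T-like cells, which turned among cells of at least 2000 UMIs and without the top cell of each library. In CD8 T-like cells its ratio was 0.742 (0.685 to 0.803), with 233 of 984 control UMIs in 1 cell. Pdcd1 had 292 and 358 CPM (1.22, 1.09 to 1.38) and Entpd1 80.3 and 123 CPM (1.53) in CD8 T-like cells, while Tnfrsf9 had 444 and 368 CPM (0.828, 0.748 to 0.918) and Cxcr3 had 39.0 and 17.6 CPM (0.451, 0.300 to 0.677). Dct had 105 of its 106 control UMIs in 1 cell and 3 UMIs in knockdown, a ratio of 0.0141 (0.00285 to 0.0422). The exhaustion list had a median of −0.07 at percentile 6.45 and the naive and memory list −0.34 (−0.52 to −0.11) at percentile 0.01 in CD8 T-like cells. CD8 subcluster 2, with Lef1 and S1pr1 among its leading genes, held 116 of 343 control and 273 of 1301 knockdown cells. Free RNA was an estimated 4.86% and 14.2% of CD8 T-like UMIs. The naive and memory list may carry both. Its members also went both ways: Cxcr3 was lower, but Ly6c2 had 770 and 2105 UMIs and Bach2 432 and 1079. The CD8 T-like totals were 1282482 and 3015990 UMIs, so neither Ly6c2 nor Bach2 was lower in CPM. The interferon list of T-like cells had a median of −0.22 (−0.29 to −0.11) and the MHC class I list −0.28 (−0.34 to −0.18), both below all 10000 random lists. The T-like chemokine list had 0.88 (0.49 to 1.13), but free RNA was an estimated 6.16% of control and 14.7% of knockdown T-like UMIs and its median was 0.17 once that was subtracted, against 1.998 with 10% free RNA subtracted from both libraries.

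In NK-like cells the cytotoxic list had a median of −0.30 (−0.36 to −0.20), below all 10000 random lists, with Gzmb at 0.6005 (0.565 to 0.638), Prf1 at 0.678 (0.615 to 0.747) and Gzma at 0.791. Klra7, an inhibitory receptor, had 440 and 205 CPM (0.466), and Cxcr4, a homing receptor, 21.8 and 70.3 CPM (3.23). Ccl5 had 1572 and 2651 CPM (1.69). The histone genes Hist1h2ap, Hist1h2ae and Hist1h1b had ratios of 0.231, 0.440 and 0.483, and the cell cycle list, at −0.47 (−0.58 to −0.30), turned with cells at equal weight. The granzyme-led NK subcluster 4 held 142 of 273 control and 217 of 467 knockdown cells and the histone-led subcluster 10 held 25 and 22, so these values carry the mix of subclusters. Free RNA was an estimated 4.46% of control and 12.3% of knockdown NK-like UMIs, and the values of this class may carry it too. Of the 98 knockdown UMIs of Ccl1 in NK-like cells, 88 lay in 1 cell.

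Dendritic-like cells of the knockdown tumour had lower RNA of MHC class II, which presents antigen to helper T cells. The list had a median of −0.43 (−0.52 to −0.39) at percentile 0.02, and H2-Ab1 had 5701 and 4037 CPM (0.708), Cd74 9466 and 7046 CPM (0.744). Ccl17 had a ratio of 0.440 and Wdfy4, which serves cross-presentation, 0.412. Ccl17 leads dendritic subcluster 10 and Wdfy4 is one of its markers, and this subcluster held 186 of 264 control and 153 of 253 knockdown cells. Ccl8 and Saa3 ranked highest, but 170 of 601 and 46 of 58 knockdown UMIs of these genes lay in 1 cell. The macrophage genes Ccl12, Selenop, Mrc1 and Ms4a7 were among the 10 highest with ratios of 6.94, 4.26, 4.16 and 3.30, but free RNA, which raises such genes and dilutes dendritic ones, was an estimated 19.3% of control and 37.7% of knockdown UMIs in these cells.

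**Figure D5:**
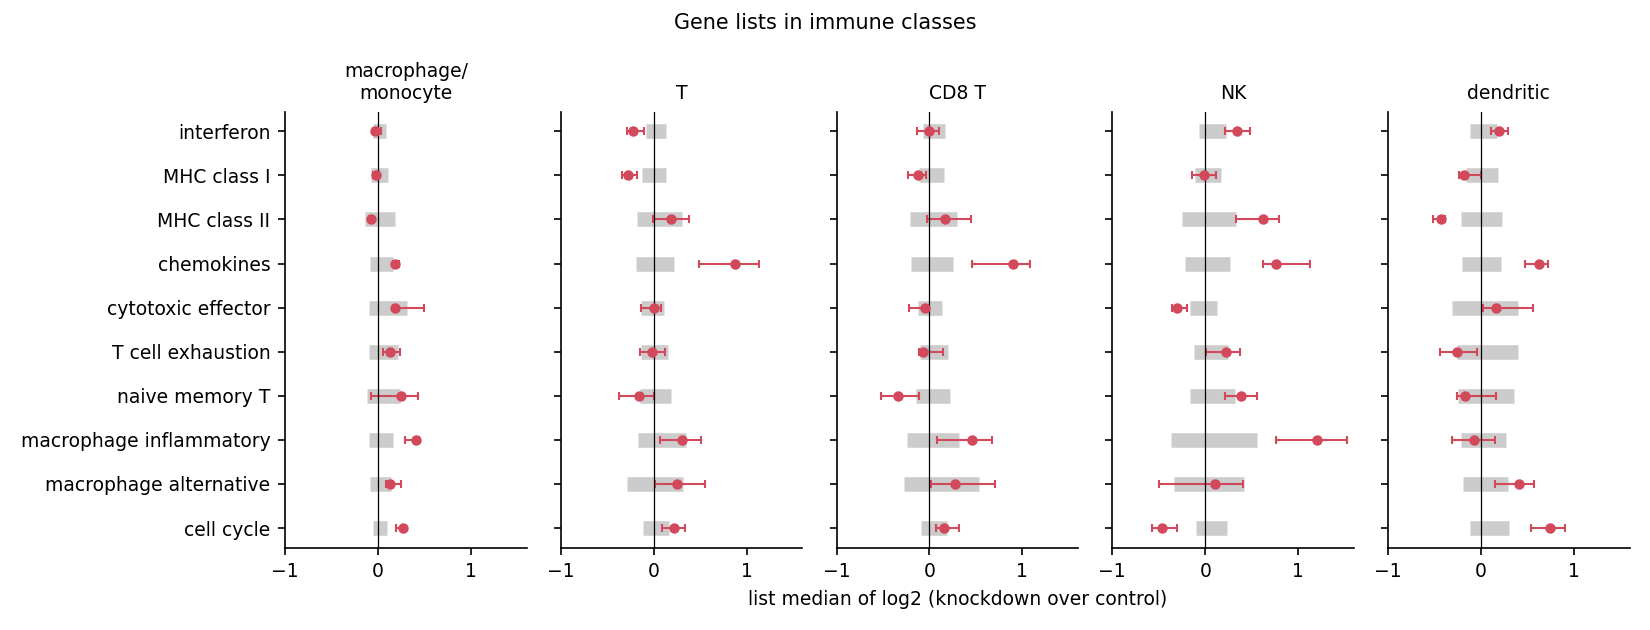
Median log2 ratio of knockdown over control of gene lists in macrophage/monocyte-like, T-like, CD8 T-like, NK-like and dendritic-like cells, with 95% counting intervals as thin bars and grey bars for the middle 95% of 10000 matched random lists. The inflammatory list of macrophages lay at 0.41, the cytotoxic list of NK-like cells at −0.30 and the MHC class II list of dendritic-like cells at −0.43.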

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

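Of 409 results with 4378 alternative values, 79.7% of the values kept their direction and size, 857 moved and 33 reversed. Of the 24 settings 9 were added after the data were seen: at least 2000 UMIs, a marker share of 15%, the shallow CD8 subcluster left out, tumour cluster 10 left out, estimated free RNA subtracted, tumour clusters at the same weight, the cell with the most UMIs left out, another seed, and the macrophage subclusters led by a dendritic marker left out. The 16 leading results, chosen after their list medians had been seen, had 177 values, of which 45 moved and 0 reversed, although the macrophage interferon and T-like cytotoxic lists lay near 0 and took both signs. Mbtps1 in tumour-like cells ranged from −1.41 to −1.21, the CD8 ratio from 2.05 to 2.96 and the macrophage ratio from 0.60 to 0.820. The median of all genes moved by over 0.1 only in NK-like cells thinned to 500 UMIs, from 0.06 to −0.06. No paired analysis was possible because each group holds 1 library and the sample numbers are in accession order. The cause of the values below was not tested.

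Where doublets were kept, the macrophage inflammatory list was 0.45, the macrophage share ratio 0.695 and Mmp12 in dendritic-like cells 0.30 in place of −2.39. Median-of-ratios scaling gave in tumour-like cells −0.23 for cholesterol, −0.27 for ER chaperones, −0.26 for MHC class I, 0.36 for cell cycle and −0.51 for matrix, and −0.073 for interferon in macrophages. With the mean of per-cell CPM, tumour MHC class I was −0.25, cell cycle 0.57, matrix −0.37, Creb3l2 −0.049 and Cxcl10 −0.067, macrophage inflammatory 0.52, and NK-like cell cycle 0.069 in place of −0.47.

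With cells thinned to 500 UMIs, tumour Mbtps1 was −1.41, MHC class I −0.22, naive T −0.51 in place of 0.45, cell cycle 0.55, matrix −0.39, Creb3l2 −0.25 and Cxcl10 −0.054. Macrophage interferon was 0.047, inflammatory 0.48, Spp1 −0.021 and Mki67 −0.0064. T-like cholesterol was 0.15 in place of −0.27, T-like lysosome −0.048, CD8 lysosome −0.035 and NK-like matrix −0.021, with NK-like AA467197 at 0.014. Dendritic-like fatty acid synthesis was −1.06, stress response −0.30, interferon −0.030, alternative macrophage −0.071, Fcrls −0.52 and Mmp12 0.87.

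With 10% free RNA subtracted the tumour matrix list was −0.19 and T-like chemokines 1.998. With the estimated share subtracted, tumour naive T was −0.61 and matrix −0.39, macrophage inflammatory 0.45, T-like stress response −0.10, chemokines 0.17 and cytotoxic 0.14, and CD8 stress response −0.010, chemokines −0.40 and inflammatory −0.55. At 2000 UMIs the T-like cytotoxic list was 0.18 and Ifng 0.087, and the share ratios were 1.26 for tumour, 1.63 for T, 2.10 for CD8 and 0.632 for neutrophils. At 1000 UMIs the macrophage share ratio was 0.770. Without the cell with the most UMIs T-like Ifng was 0.034.

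Without tumour cluster 10 the tumour ER chaperones were −0.16, MHC class I −0.19, cell cycle 0.33 and matrix −0.37. At the same cluster weight, cholesterol was −0.073, ER chaperones −0.14, lysosome 0.04, MHC class I −0.10, cell cycle 0.18, matrix −0.15 and B2m 0.13. Without the subclusters led by a dendritic marker macrophage H2-Ab1 was 0.040. Without the test against empty droplets the share ratios were 1.54 for tumour, 0.60 for macrophages, 1.81 for T and 2.14 for CD8. Among immune-like cells the macrophage ratio was 0.820, and without the shallow CD8 subcluster the CD8 ratio was 2.05. Without thinning the Cxcl9 share of macrophages differed by 7.72 points, the tumour Cxcl10 share by −2.87 in place of 3.099 and the tumour Cd274 share by −3.55 in place of 1.34.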

Other observations

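Regulatory T-like cells of the knockdown library had a cytotoxic list median of −0.76 (−1.07 to −0.59), below all 10000 random lists, with 9 of 12 members at least 1.5 times lower. Endothelial-like cells had a cell cycle median of 0.71 (0.44 to 0.86), above all random lists. Fibroblast-like cells had a cell cycle median of 0.67. Free RNA was an estimated 28.1% of control and 43.9% of knockdown UMIs in endothelial-like cells, and 14.4% and 23.99% in fibroblast-like cells. Neutrophil-like cells had an MHC class II median of −1.69 (−1.92 to −1.24), with 7 of 7 members lower. There were 61 control and 191 knockdown cells of this class, with an estimated 6.29% and 23.9% of free RNA. In regulatory T-like cells free RNA was an estimated 8.42% and 18.5%. Epidermis-like cells had a cholesterol synthesis median of −0.53, with 10 of 22 members lower, and an interferon median of 0.75, but free RNA was an estimated 15.6% of control and 66.0% of knockdown UMIs there.

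Of the tests below, those on regulatory T and NK cells, on fibroblast RNA and on the whole library were chosen only after the result was seen. The CD8 share was higher in the knockdown. If shallow barcodes had made the difference, it should vanish among deep cells, but among cells of at least 2000 UMIs the ratio was still 2.10 (1.73 to 2.55). If fewer macrophages had raised every other immune class alike, regulatory T and NK cells would show it. Their ratios among immune-like cells were 1.13 (0.843 to 1.51) and 1.33 (1.09 to 1.64), against 2.96 (2.54 to 3.46) for CD8 T-like cells. Some other classes rose as well, with 2.44 for neutrophil-like and 4.01 for gamma-delta T-like cells, while dendritic-like cells had 0.748. A difference between 2 tumours or their handling remains possible and was not tested.

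The lower matrix list of tumour-like cells could come from less fibroblast RNA in the knockdown. Among the members that were at least 1.5 times lower, the 3 of at least 100 CPM would need a fibroblast share of at least 3.29%, while Col1a1 allows 0.756%, so all 3 lie beyond it. For those below 100 CPM the smallest needed share was 0.0755%, and 3 of 7, Col1a1 left aside, lie beyond what it allows, so the others cannot be told apart from fibroblast RNA. The mix of tumour clusters is another explanation: at the same weight the median was −0.15 (−0.17 to −0.09), so cluster mix and expression within cells cannot be told apart.

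The lower cholesterol synthesis list could follow from less cleavage of SREBP2, from the mix of clusters or from depth. Among tumour-like cells of 10000 to 20000 UMIs the median was −0.16 (−0.21 to −0.08) against −0.18 in the whole class. By the rule as first written, this went against depth as the whole cause. The window lies below the median of control tumour-like cells, 21507 UMIs, and around that of knockdown ones, 12738.5 UMIs. Its cell cycle median was 1.44 against 0.41 in the whole class. The window thus sets unlike cells side by side and cannot decide on depth. At the same cluster weight the cholesterol median was −0.073 (−0.11 to −0.04), so cluster mix, depth and less cleavage cannot be told apart. A shift common to every class would act on macrophages too, but their median was 0.10, which argues against it. T-like cells, at −0.27 (−0.42 to −0.05), and epidermis-like cells, at −0.53, were low as well without a clearly lower Mbtps1. The T-like value turned to 0.15 with thinned cells. Free RNA was an estimated 15.6% of control and 66.0% of knockdown epidermis-like UMIs. A shift shared by some classes thus stays open, with these limits on both values.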
